A study of Mus musculus with 12 samples.

How the data were processed

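Contacts between chromatin and the nuclear lamina were mapped by DamID in mouse embryos, using a fusion of the bacterial adenine methyltransferase Dam to lamin B1, which methylates DNA that lies near the lamina. Per the labels' protocols, zygotes were injected with a control siRNA or an siRNA against Rif1 (20 µM, 17 to 18 h after hCG), and late 2-cell embryos were injected at 46 to 48 h with mRNA for the degron-tagged Dam-LaminB1 fusion (20 ng/µL), the auxin receptor Tir1 (250 ng/µL) and a membrane eGFP marker (100 ng/µL). Auxin (500 µM), which degrades the fusion, was removed at 54 h for 4-cell embryos and at 66 h for 8-cell embryos. Embryos were collected at 60 to 62 h or 72 to 74 h, and each replicate pooled 16 to 24 blastomeres. These came from 4 to 6 embryos at the 4-cell stage and from 2 to 3 embryos at the 8-cell stage. The 12 samples form 4 groups of 3 replicates: siControl 4-cell, siRif1 4-cell, siControl 8-cell and siRif1 8-cell.

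The authors deposited, for each group, a list of lamina-associated domains (LADs) made from all 3 replicates, so 4 lists were analysed. Each deposited list gives the start and end of every LAD on a 100-kb grid, and its score field is 0 throughout and was not used. Reads were processed with Trimmomatic, Bowtie2, SAMtools and Picard against mm10 (GRCm38), per the submitters' processing notes, which give no versions. The LAD caller, its settings and any correction for unfused Dam are not given in the sources used here. LADs lie on chromosomes 1 to 19 in all 4 lists, and chromosome X was not analysed here. Read depth per replicate is unknown from the lists, so no interval for counting error can be given. A threshold that depends on depth or on the spread between replicates would change how much of the genome is called, and the lists do not show whether it did.

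Coordinates are 1-based on GRCm38. The span of a chromosome runs from the first to the last LAD of any list, 2384.9 Mb in all, and coverage is the percent of this span in LADs. Pairs of lists were compared by the bases they share, by bases in one list alone, by the Jaccard index (shared bases over bases in either list) and by the number of LADs with at least 50% of their length in the other list. Chance overlap was taken from 10000 circular shifts of one list along each chromosome, given as the mean and the central 95% range. For differences between overlaps, the chromosomes were resampled 10000 times. Pooled lists allow no test between conditions, so no p-value is given, and SDs over the 19 chromosomes describe chromosomes, not replicates.

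Genes were taken from the RefSeq annotation of GRCm38.p6, leaving out 333 of 47042 entries whose coordinates belong to scaffolds. The annotation table used here gives no strand, so the transcription start planned for placing a gene could not be known, and a gene was counted in a LAD when its midpoint lay in it. This is a departure from the design. Of the annotated genes, 20144 protein-coding genes lie in the span. From the design, 26 gene lists were fixed and 25 were tested: pluripotency and inner cell mass, trophectoderm, primitive endoderm, 2-cell stage and zygotic genome activation, germ layer and neural regulators, long neuronal and adhesion genes, nuclear lamina and envelope, replication factors, imprinted genes, ribosomal proteins, proteasome, mitochondrial complex I, olfactory receptors, vomeronasal receptors, zinc finger proteins, Hox, histone and protocadherin clusters, keratins, beta defensins, Pramel, Obox, serpins, C-type lectin and killer receptors, and cytochrome P450 genes. The keratin list also holds the keratin-associated genes, and "keratin genes" below means both. The list of X-linked Rhox, Mage and Xlr families was not analysed here. A list is called outside the range of positions when its share in LADs lies outside the central 95% range of 10000 shifts. For regions that differ between lists, shifts ran along the bins outside LADs of one list or inside LADs of the other, and lists with fewer than 5 genes there were not tested. At 25 lists, chance alone puts 1.25 outside the range if genes lie without regard to LADs, and more lists can fall below the range of positions if genes avoid them. Protein-coding genes as a whole avoid LADs, so a second set of 10000 shifts along the order of genes was added after the data were examined. It compares a list with other genes of its chromosomes and keeps its clustering.

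Named genes follow a rule fixed in the design: the 5 longest differing stretches in each direction with up to 3 named protein-coding genes, members of lists of at most 40 genes whose state differs (at most 25 per comparison, in the order of the lists), Rif1, Lmnb1 and the lamina list, and the longest LAD of each list. Genes outside this rule are said to be chosen after their values were seen. Some genes and a stretch that the rule names are not reported here.

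Alternatives fixed in advance were LADs of at least 300 kb, gaps of up to 200 kb bridged, differing stretches of at least 300 kb, other overlap criteria (1 bp or 80% of the LAD), 1000 random placements of LADs in place of shifts, each chromosome left out in turn, 50% of the gene body in place of the midpoint, and all annotated genes. Added after the data were examined were coverage of the span of annotated genes, genes placed by their lower or higher coordinate, odds ratios, correlations and shares in place of the Jaccard index, shifts within the bins outside or inside siControl 4-cell LADs, and the shifts along the order of genes. Base composition was not computed, because no genome sequence was used here.

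The calculations were tested on simulated data first. All planted differing stretches in the siControl 4-cell list were recovered (100% of 114), which checks the code alone, as no noise was added. Of 500 clustered lists of positions, placed at random without regard to genes, 4.4% fell outside the range of positions. Of 500 lists made of runs of neighbouring genes, 2.2% fell outside the range of other genes. Lists of 50 scattered positions were called in 70.4% of simulations at 0.5 times the coverage, 21.4% at 0.75 times, 63.4% at 1.5 times and 99.8% at 2.0 times. These simulations used the siControl 4-cell list alone. Planted shares in lists of fewer than 50 genes or of clustered genes were not simulated, so these rates do not apply to such lists. Since real genes avoid LADs, the 4.4% does not say how often an unrelated gene list would fall below the range of positions. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.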

Results

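LADs were compared between mouse embryos given an siRNA against Rif1, a chromatin protein that acts in replication timing, and embryos given a control siRNA, at the 4-cell and the 8-cell stage. Each of the 4 groups had 3 replicates, and each group's LADs were available as a list pooled over them. The lists therefore carry no replicate error and no read depth, and no p-value is given for any difference between groups. Nothing in the labels allows a check of whether replicates came from separate collections of embryos. The comparisons, gene lists and alternatives were chosen before the data were examined, except where stated. The lists hold no RNA levels and do not check the knockdown. Rif1 itself (chromosome 2, 52072815 to 52126769) lay outside LADs in all 4 lists.

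LADs covered least of the genome in siControl 4-cell embryos. In that group 601 LADs covered 785.7 Mb, 32.9% of the span, with a mean of 33.2% ± 8.51 over chromosomes (SD, 19 chromosomes). In siRif1 4-cell embryos 644 LADs covered 1038.4 Mb (43.5%), with a mean of 43.2% ± 9.96. At the 8-cell stage 746 siControl LADs covered 1066.7 Mb (44.7%, mean 44.6% ± 7.45), and 738 siRif1 LADs covered 1023.5 Mb (42.9%, mean 42.0% ± 7.40). Median LAD lengths were 0.9 Mb in siControl 4-cell, 1.1 Mb in siRif1 4-cell, 1 Mb in siControl 8-cell and 0.9 Mb in siRif1 8-cell embryos. The longest LAD of each list lay on chromosome 1 (156600001 to 166500000) in siControl 4-cell, on chromosome 9 (3000001 to 14200000) in siRif1 4-cell, on chromosome 7 (82500001 to 92600000) in siControl 8-cell and on chromosome 2 (132800001 to 150100000, 17.3 Mb) in siRif1 8-cell embryos.

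**Figure D1:**
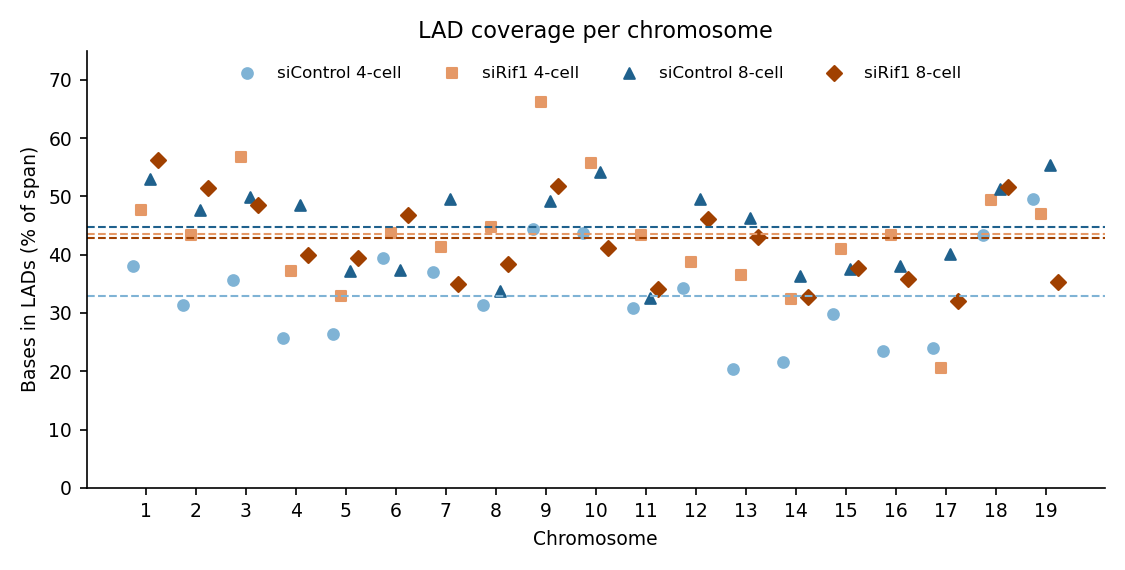
Percent of each chromosome's span in LADs (vertical axis) for chromosomes 1 to 19 (horizontal axis); each point is the pooled list of a group and dashed lines mark the percent over all chromosomes. Points of siControl 4-cell embryos lie below those of siRif1 4-cell embryos on 17 of 19 chromosomes.

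At the 4-cell stage the question was which regions change lamina association when Rif1 is depleted. Of the long neuronal and adhesion genes, 5 were LAD in siRif1 and not in siControl embryos, among them Cntnap5a, the synaptic adhesion gene Nlgn1, the scaffold gene Dlg2 and Cntn5. These 5 of the 26 outside siControl LADs lie within the ranges of positions (7.69 to 42.3%) and of other genes (0 to 26.9%). None of the 37 genes of this list went the other way, and 11 were LAD in both. Early lineage genes were found on both sides. The pluripotency-associated Dppa2 and Dppa4 and the endoderm regulators Gata6 and Sox17 were LAD in siControl alone, whereas Nr5a2, Zfp42, Pdgfra and Dab2 were LAD in siRif1 alone.

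Of the 20 pluripotency genes, 2 were LAD in siControl alone, 2 in siRif1 alone, 1 in both and 15 in neither. The 12 primitive endoderm genes split 2, 2, 2 and 6 in that order. The 16 trophectoderm genes did not differ, with 3 LAD in both lists. Of 26 genes of the 2-cell stage and zygotic genome activation, 7 were LAD in both, Pramel16 and Arg2 in siControl alone, and Zfp42 and Duxf3 in siRif1 alone. Of 24 germ layer and neural regulators, Pax3 was LAD in siControl alone. The neural regulators Lhx2 and Nkx2-1 and the muscle regulator Myf5 were LAD in siRif1 alone. Among nuclear envelope genes, Sun2 and Lmnb1 were LAD in siControl alone. Of 29 replication factors, 3 were LAD in siControl alone, among them the origin recognition gene Orc4, 2 in siRif1 alone and 3 in both. Of the clustered families, Hox genes were LAD in siControl alone in 9 of 39 cases and in siRif1 alone in 0, serpins in 0 and 10 of 62, vomeronasal receptor genes in 23 and 40 of 347, keratin genes in 7 and 10 of 112 and cytochrome P450 genes in 8 and 14 of 99. The 9 Hox genes are those of the HoxD cluster, a single locus on chromosome 2 (74668225 to 74765142). In either direction, the shares of these families lay within the ranges of positions and of other genes. For the Hox genes in siControl LADs, the range of positions was 0 to 100%, so no share could lie outside it.

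The longest stretch that was LAD in siRif1 alone spanned 3.7 Mb of chromosome 9 (9600001 to 13300000) and held Cntn5, Jrkl and Ccdc82. The next were on chromosome 11 at 12800001 to 16400000 (Pom121l12, Vstm2a) and at 36000001 to 39300000 (Tenm2), and on chromosome 3 at 59100001 to 62000000 (17 genes, including Med12l and P2ry14) and at 75900001 to 78800000 (Golim4, Fstl5). The longest stretch that was LAD in siControl alone spanned 2.8 Mb of chromosome 18 (10400001 to 13200000). It held 19 protein-coding genes, among them Greb1l, Esco1, Snrpd1 and Gata6, and was outside LADs in all 3 other lists. The remaining 4 were on chromosome 1 at 119600001 to 121500000 (Ptpn4, Tmem177, Cfap221), chromosome 13 at 91200001 to 93100000 (Ssbp2, Acot12, Zcchc9), chromosome 18 at 64400001 to 66300000 (Fech, Nars, Atp8b1) and chromosome 2 at 143000001 to 144700000 (Snrpb2, Otor, Pcsk2).

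**Figure D2:**
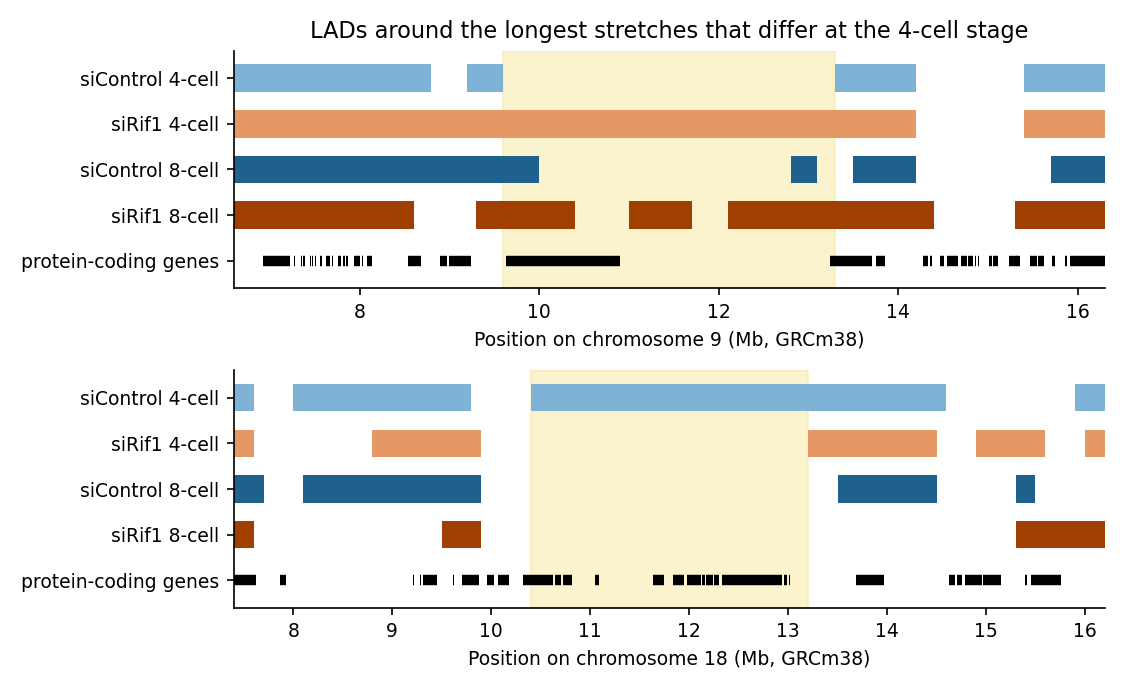
LADs of the 4 lists (coloured bars) and protein-coding genes (black) along chromosome 9 and chromosome 18, positions in Mb on GRCm38; shading marks the longest stretch that is LAD in siRif1 4-cell alone (3.7 Mb) and in siControl 4-cell alone (2.8 Mb). The shaded stretch of chromosome 18 is free of LADs in the 3 lists other than siControl 4-cell.

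The siRif1 list covered 252.7 Mb (32.2%) more than the siControl list. The mean difference over chromosomes was 10.1 ± 7.05 percentage points (SD), and coverage was higher on 17 of 19 chromosomes, most on chromosome 9 (21.8 points). Chromosome 17 had the lowest difference, at -3.40 points. The lists shared 630.4 Mb, 408 Mb were LAD in siRif1 alone and 155.3 Mb in siControl alone. The Jaccard index was 52.8%, against a mean of 24.2% and a range of 22.4 to 26.3% for shifted lists. Of the siControl LADs, 485 of 601 (80.7%) were shared, and of the siRif1 LADs 361 of 644 (56.1%). LAD in siRif1 alone comprised 676 stretches, of which extensions of a siControl LAD at a border made up 50.0% of the bases, closures of a gap between siControl LADs 25.2% and freestanding stretches 24.8%.

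Olfactory receptor genes, a large clustered family, lay more often than other genes in the stretches that were LAD in siRif1 alone. Of the 829 outside siControl LADs, 156 (18.8%) were in them, above the range of other genes (4.46 to 16.8%, all protein-coding genes 9.79%). This share was within the range of positions (12.7 to 44.3%) and below the mean of the shifts (27.4%). None of 60 ribosomal protein genes lay in these stretches, below both ranges (other genes 3.33 to 18.3%, positions 15 to 36.7%). Proteasome genes (3 of 40), complex I genes of the respiratory chain (1 of 32), imprinted genes (0 of 26) and zinc finger genes (15 of 293) were below the range of positions but within that of other genes. In the other direction, 49 of 84 zinc finger genes in siControl LADs (58.3%) were outside siRif1 LADs, above both ranges (other genes 23.8 to 56.0%). Ribosomal protein (6 of 13) and complex I genes (7 of 12) were above the range of positions alone. Fewer olfactory receptor genes (32 of 272) and none of the 11 long neuronal genes in siControl LADs were outside siRif1 LADs, below the range of other genes (15.8 to 50.0% and 9.09 to 63.6%) and within that of positions (5.51 to 41.9% and 0 to 45.5%). In total, 5 of 25 lists lay outside the range of positions in the first direction and 3 of 16 in the second. With other genes as reference, 2 and 3 did.

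At the 8-cell stage the lists differed on both sides by similar lengths. Sox2 and Nanog, both core pluripotency genes, and the trophectoderm regulator Cdx2 were LAD in siRif1 and not in siControl embryos. The trophectoderm genes Gata3 and Ascl2 and the 2-cell stage genes Zscan4a, Zscan4b, Zscan4c, Zscan4d, Usp17lc, Usp17ld and Tcstv3 were LAD in siControl alone. Clustered families differed in blocks. Of 347 vomeronasal receptor genes, 97 were LAD in siControl alone and 1 in siRif1 alone, and of 112 keratin genes 44 and 2. In contrast, 36 of 51 clustered protocadherin genes and 16 of 60 C-type lectin and killer receptor genes were LAD in siRif1 alone, against 0 and 1 in siControl alone.

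Long neuronal genes were found on both sides, with 7 of 37 LAD in siRif1 alone, among them Cntnap5b, Lrp1b, Cntnap2, Ctnna2, Csmd1 and Cntn5, and 4 in siControl alone, among them Ptprd and Cntn4. Of the 2-cell stage genes, Tdpoz3, Tdpoz4 and Tcstv1 were LAD in siRif1 alone. The 12 primitive endoderm genes did not differ. Of the Hox genes, the 9 of the HoxD cluster were LAD in siControl alone and the 9 of the HoxC cluster in siRif1 alone. Serpin genes were LAD in siControl alone in 13 of 62 cases and in siRif1 alone in 5, Pramel genes in 7 and 0 of 45, and cytochrome P450 genes in 8 and 8 of 99. Beta defensin genes numbered 2 and 0 of 42, histone genes 0 and 0 of 77, and Obox genes 1 and 0 of 6.

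The longest stretch that was LAD in siRif1 alone lay on chromosome 11 (12300001 to 15500000, 3.2 Mb, Cobl and Pom121l12). Others lay on chromosome 8 at 98300001 to 101400000 (Cdh8, a cadherin gene), chromosome 17 at 59400001 to 62300000 (no protein-coding gene), chromosome 5 at 61200001 to 64000000 (G6pd2, Arap2, Dthd1) and chromosome 1 at 47600001 to 49900000. LAD in siControl alone were chromosome 19 at 17100001 to 21000000 (3.9 Mb, including Gcnt1, Rfk and Pcsk5), chromosome 10 at 51000001 to 53600000 (Lilr4b, Lilrb4a, Fam162b) and 35500001 to 37700000 (Amd2, Hs3st5, Hdac2), chromosome 13 at 31000001 to 33500000 (the forkhead genes Foxq1, Foxf2 and Foxc1) and chromosome 17 at 9100001 to 11200000 (Pabpc6, Qk).

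LAD bases dropped by 43.2 Mb from siControl to siRif1 embryos (-4.05%), with a mean difference of -2.65 ± 7.40 percentage points over chromosomes. Coverage was lower on 10 of 19 chromosomes, most on chromosome 19 (-20.1 points), and was most above siControl on chromosome 6 (9.43 points). The mean difference is small beside this spread between chromosomes. The total also depends on chromosome 7, without which it was -22.8 Mb. The lists shared 750.5 Mb, with 273 Mb LAD in siRif1 alone and 316.2 Mb in siControl alone. The Jaccard index was 56.0% (shifted lists 28.6%, range 26.7 to 30.7%), and 501 of 746 siControl LADs (67.2%) and 508 of 738 siRif1 LADs (68.8%) were shared.

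Outside siControl 8-cell LADs, 149 of 454 olfactory receptor genes (32.8%), 7 of 19 long neuronal genes (36.8%) and 16 of 32 C-type lectin and killer receptor genes (50.0%) were LAD in siRif1. These shares were above the ranges of other genes (3.30 to 22.9%, 0 to 31.6% and 0 to 47.0%), and within the ranges of positions. Ribosomal protein genes (1 of 66) were below both. Proteasome (3 of 46) and zinc finger genes (18 of 296) were below the range of positions alone. Of 81 zinc finger genes in siControl LADs, 42 (51.9%) were outside siRif1 LADs, above the range of positions (13.6 to 50.6%) but not that of other genes. The 2-cell stage genes LAD in siControl alone (7 of 13, 53.8%) and the pluripotency genes LAD in siRif1 alone (2 of 18, 11.1%) were within both ranges. The blocks of vomeronasal, keratin, protocadherin, Pramel, serpin and Hox genes lay within both ranges. For protocadherin genes in siRif1 alone and Hox genes in siControl alone, the range of positions was 0 to 100%, so no share could lie outside it. For keratin genes in siControl alone it was 0 to 92.6%, which leaves little room for a call.

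**Figure D3:**
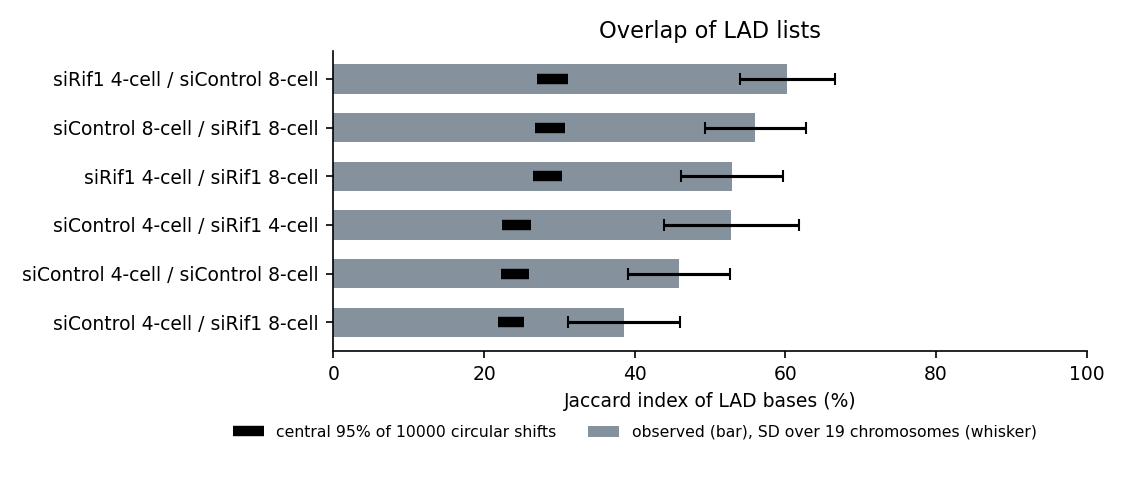
Jaccard index of LAD bases (horizontal axis, %) for the 6 pairs of lists; bars are observed values, whiskers the SD over 19 chromosomes and black blocks the central 95% range of 10000 circular shifts. All 6 observed values, from 38.6 to 60.3%, lie above the shifted ones.

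From the 4-cell to the 8-cell stage, control embryos had more chemosensory receptor genes in LADs. Of 829 olfactory receptor genes outside siControl 4-cell LADs, 418 (50.4%) were LAD at the 8-cell stage, and of 295 vomeronasal receptor genes 188 (63.7%), against 14.8% of all protein-coding genes. Keratin genes (55 of 92), cytochrome P450 genes (25 of 70) and long neuronal genes (8 of 26), such as Cntnap5a, Ptprd, Cntn4, Cntn6, Dlg2, Cdh9 and Csmd3, were also in LADs more often than other genes. None of 32 complex I genes and none of 74 histone genes was, with 2 of 60 ribosomal protein and 1 of 40 proteasome genes.

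These shares were outside the ranges of other genes, which reached 28.5% for olfactory, 35.3% for vomeronasal, 39.1% for keratin, 31.4% for cytochrome P450 and 26.9% for long neuronal genes. They began at 3.13% for complex I, 1.35% for histone, 6.67% for ribosomal protein and 5.00% for proteasome genes. Against positions, the vomeronasal share was above its range (15.3 to 52.9%) and the other 4 raised shares were within theirs. The ribosomal protein, proteasome, complex I and histone shares were below both. Pluripotency genes (0 of 17), germ layer and neural regulators (1 of 19), replication factors (2 of 23) and zinc finger genes (37 of 293) were below the range of positions only. In the reverse direction, none of the 52 vomeronasal receptor genes in 4-cell LADs was outside 8-cell LADs, below both ranges. Olfactory receptor genes (43 of 272, range 19.9 to 59.6%) and long neuronal genes (1 of 11, range 18.2 to 72.7%) were below the range of other genes and within that of positions. Ribosomal protein (8 of 13), proteasome (7 of 9) and zinc finger genes (40 of 84) in 4-cell LADs were outside 8-cell LADs more often than the range of positions, but not than other genes.

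Among named genes, Sox2, Fgfr2, Sox17, Gata6, Arg2, Eif1a, Pax6 and Kcnip4 were LAD in control embryos at the 4-cell stage alone. Ascl2, the trophectoderm regulator Eomes, Zfp352, Zscan4c, Zscan4d, Usp17lc, Usp17ld and Tcstv3 were LAD at the 8-cell stage alone. The longest stretches LAD at the 8-cell stage alone lay on chromosome 13 at 78600001 to 82400000 (3.8 Mb, Arrdc3, Adgrv1, Lysmd3), chromosome 7 at 85000001 to 88400000 (34 genes, including Vmn2r66, Vmn2r67 and Vmn2r68), chromosome 12 at 45200001 to 48500000 (Nova1), chromosome 14 at 36100001 to 39300000 (Ccser2, Rgr, Lrit1) and chromosome 4 at 74700001 to 77800000 (Dmac1, Ptprd). LAD at the 4-cell stage alone were chromosome 18 at 10400001 to 13500000 (3.1 Mb, around Gata6), chromosome 9 at 54000001 to 56600000 (Tnfaip8l3, Cyp19a1, Gldn), chromosome 8 at 89500001 to 91900000 (Tox3, Chd9, Rbl2), chromosome 3 at 102800001 to 105100000 (Sycp1, Nr1h5, Sike1) and chromosome 7 at 109000001 to 111200000 (Tub, Ric3, Lmo1).

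LAD bases in control embryos were 281 Mb (35.8%) higher at the 8-cell stage, with a mean difference of 11.4 ± 7.11 percentage points over chromosomes and higher coverage on 18 of 19, most on chromosome 13 (25.98 points). The stages shared 582.6 Mb, 484.1 Mb were LAD at the 8-cell stage alone and 203.1 Mb at the 4-cell stage alone. The Jaccard index was 45.9% (shifted lists 24.0%, range 22.3 to 25.96%), and 459 of 601 4-cell LADs (76.4%) and 378 of 746 8-cell LADs (50.7%) were shared.

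In siRif1 embryos, olfactory receptor genes were again LAD more often at the 8-cell stage. Of 705 outside 4-cell LADs, 295 (41.8%) were LAD at the 8-cell stage, above the ranges of positions (7.52 to 36.9%) and of other genes (4.54 to 26.1%). Vomeronasal receptor genes (92 of 278, 33.1%) were above the range of other genes (2.88 to 21.9%) alone. Ribosomal protein (2 of 66), proteasome (1 of 41) and zinc finger genes (26 of 327) were below the range of positions but not that of other genes. Of the olfactory receptor genes in 4-cell LADs, 77 of 396 (19.4%) were outside 8-cell LADs, below the range of other genes (19.9 to 44.9%) and within that of positions (14.9 to 50.3%). The other 14 lists tested in that direction lay within both ranges. Nanog, Dppa2, Dppa4, Cdx2, Eomes, Zfp352, Tdpoz3, Tdpoz4, Pramel16, Tcstv1 and Pax3 were LAD at the 8-cell stage alone. Nr5a2, Zfp42, Gata3, Fgfr2, Pdgfra, Dab2, Zscan4a, Zscan4b, Duxf3, Eif1a, Lhx2, Pax6 and Myf5 were LAD at the 4-cell stage alone.

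Among the longest stretches LAD in siRif1 embryos at the 8-cell stage alone were chromosome 12 at 92400001 to 96700000 (4.3 Mb, Flrt2), chromosome 17 at 58900001 to 62300000 (Pdzph1, Nudt12), chromosome 5 at 145300001 to 148600000 (41 genes, including Cyp3a57, Cyp3a16 and Cyp3a41b) and chromosome 4 at 78400001 to 80700000. LAD at the 4-cell stage alone were chromosome 13 at 15600001 to 18600000 (Inhba, Sugct, Mplkip), chromosome 10 at 27500001 to 30200000 (Ptprk, Themis, Soga3) and 36300001 to 39000000 (Hs3st5, Hdac2, Marcks), chromosome 16 at 14100001 to 16800000 (Marf1, Nde1, Myh11) and chromosome 11 at 42600001 to 45200000 (Atp10b, Pttg1, Slu7). LAD bases differed by -14.9 Mb (-1.43%) between the stages, and without chromosome 10 by 3.7 Mb. Coverage was higher on 10 chromosomes and lower on 9. The Jaccard index was 52.9% (shifted lists 28.3%, range 26.5 to 30.4%), and 432 of 644 4-cell LADs (67.1%) and 467 of 738 8-cell LADs (63.3%) were shared.

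Regions that differed after siRif1 at the 4-cell stage were then compared with the state that control embryos had at the 8-cell stage. Of the 408 Mb that were LAD in siRif1 4-cell and not in siControl 4-cell embryos, 65.3% were siControl 8-cell LADs. Of the 1191.2 Mb outside LADs in both 4-cell lists, 18.3% were. Shifts of the 8-cell list gave 45.0% (range 41.8 to 48.3%) in place of 65.3%, and shifts within the bases outside siControl 4-cell LADs, added after the data were examined, gave 30.9% (27.9 to 34.3%). Of the 155.3 Mb that were LAD in siControl 4-cell alone, 63.1% lay outside siControl 8-cell LADs, against 16.7% of the 630.4 Mb LAD in both 4-cell lists. In place of 63.1%, shifts of the 8-cell list gave 54.8% (49.6 to 59.9%), and shifts within siControl 4-cell LADs gave 26.2% (22.4 to 30.3%). The siControl 4-cell list is used on both sides of these comparisons, so regions miscalled in that list alone would raise both shares. The match was not particular to control embryos. Of the 408 Mb, 196.1 Mb were LAD in both 8-cell lists, 70.3 Mb in siControl 8-cell alone and 63.5 Mb in siRif1 8-cell alone. Of the 155.3 Mb, 78.6 Mb lay outside LADs of both 8-cell lists, 19.4 Mb outside those of siControl 8-cell alone and 26.8 Mb outside those of siRif1 8-cell alone. The siRif1 4-cell and siControl 8-cell lists had the highest Jaccard index of the 6 pairs, 60.3%.

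Protein-coding genes were scarcer inside LADs than outside in every group, and least so in siControl 4-cell embryos. In that group, LADs held 6.34 genes per Mb and the rest of the span 9.48. The corresponding densities were 4.66 and 11.4 in siRif1 4-cell, 4.96 and 11.3 in siControl 8-cell and 4.77 and 11.2 in siRif1 8-cell embryos. LADs held 24.7%, 24.0%, 26.3% and 24.2% of genes in the same order, all below the shifted lists, whose ranges began at 30.4%, 40.2%, 41.5% and 39.3%. At the 4-cell stage, stretches LAD in siRif1 alone held 3.64 genes per Mb (1484 genes) and stretches LAD in siControl alone 10.5 (1628 genes), against 5.31 in LADs of both and 11.5 outside both. At the 8-cell stage the densities were 5.41 in siRif1 alone and 5.97 in siControl alone. In control embryos, stretches LAD at the 4-cell stage alone held 9.51 genes per Mb and those LAD at the 8-cell stage alone 4.64. In siRif1 embryos these values were 5.32 and 5.74.

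**Figure D4:**
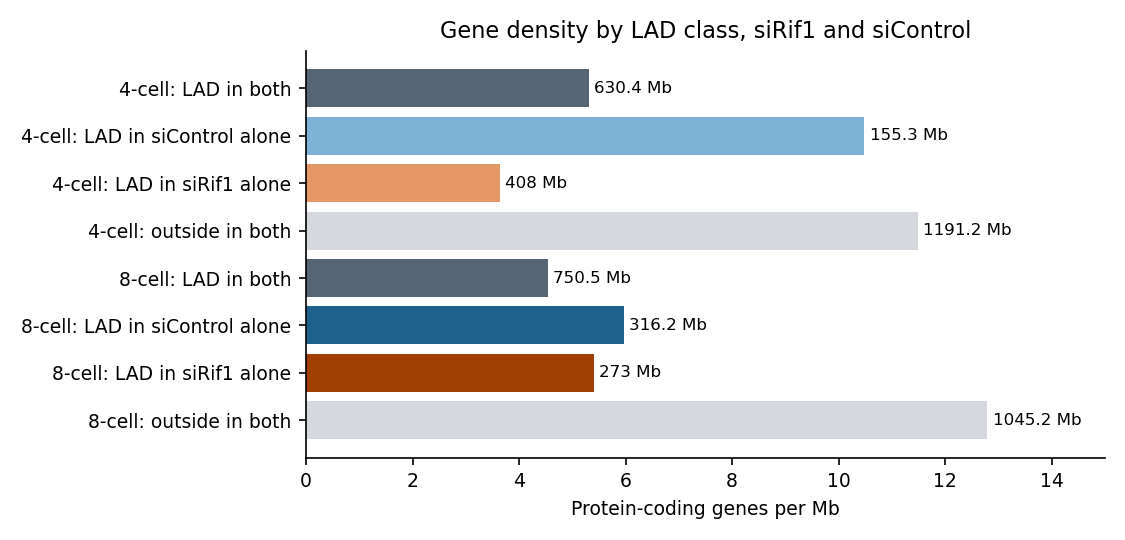
Protein-coding genes per Mb (horizontal axis) in bases that are LAD in both lists, in one list alone or in neither, for siControl and siRif1 at each stage, with the Mb of each class beside its bar. Bases LAD in siControl 4-cell alone held 10.5 genes per Mb and those LAD in siRif1 4-cell alone 3.64.

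Across the 4 lists, ribosomal protein and histone genes stood apart by low shares in LADs and chemosensory receptor genes by high shares at the 8-cell stage. Ribosomal protein genes were in LADs in 17.8% of cases in siControl 4-cell, 9.59% in siRif1 4-cell, 9.59% in siControl 8-cell and 5.48% in siRif1 8-cell embryos, below the range of positions each time, and below that of other genes in the latter 3. Histone genes were at 3.90% and then 2.60% in the other 3 lists, below both ranges in those 3. Vomeronasal receptor genes were at 14.99%, 19.9%, 69.2% and 41.5%, above both ranges in siControl 8-cell embryos alone. Olfactory receptor genes were at 24.7%, 36.0%, 58.8% and 55.8%, above the range of other genes in the latter 3 and within that of positions in all 4.

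Long neuronal genes were at 29.7%, 43.2%, 48.6% and 56.8%, above the range of other genes in both 8-cell lists. In siControl 8-cell embryos keratin (60.7%) and Pramel genes (66.7%) were above the range of other genes, and proteasome (6.12%) and complex I genes (13.6%) below both ranges. In siRif1 4-cell embryos zinc finger genes (13.3%) were below both ranges. Shares below the range of positions alone were found for pluripotency genes (15% in siRif1 4-cell, 10.0% in siControl 8-cell), replication factors (17.2%, 17.2% and 13.8% in siRif1 4-cell, siControl 8-cell and siRif1 8-cell), imprinted genes (10.0%, 16.7% and 10.0% in the same lists), germ layer regulators and nuclear envelope genes in siControl 8-cell (20.8% and 16.7%), and beta defensins in siRif1 4-cell (0 of 42). Proteasome and complex I genes in siRif1 4-cell (16.3% and 13.6%) and siRif1 8-cell embryos (10.2% and 25%) and zinc finger genes in both 8-cell lists (21.5% and 15.1%) also were. Outside the range of positions were 1, 9, 11 and 7 of 25 lists, and outside that of other genes 0, 4, 9 and 4, in siControl 4-cell, siRif1 4-cell, siControl 8-cell and siRif1 8-cell embryos.

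**Figure D5:**
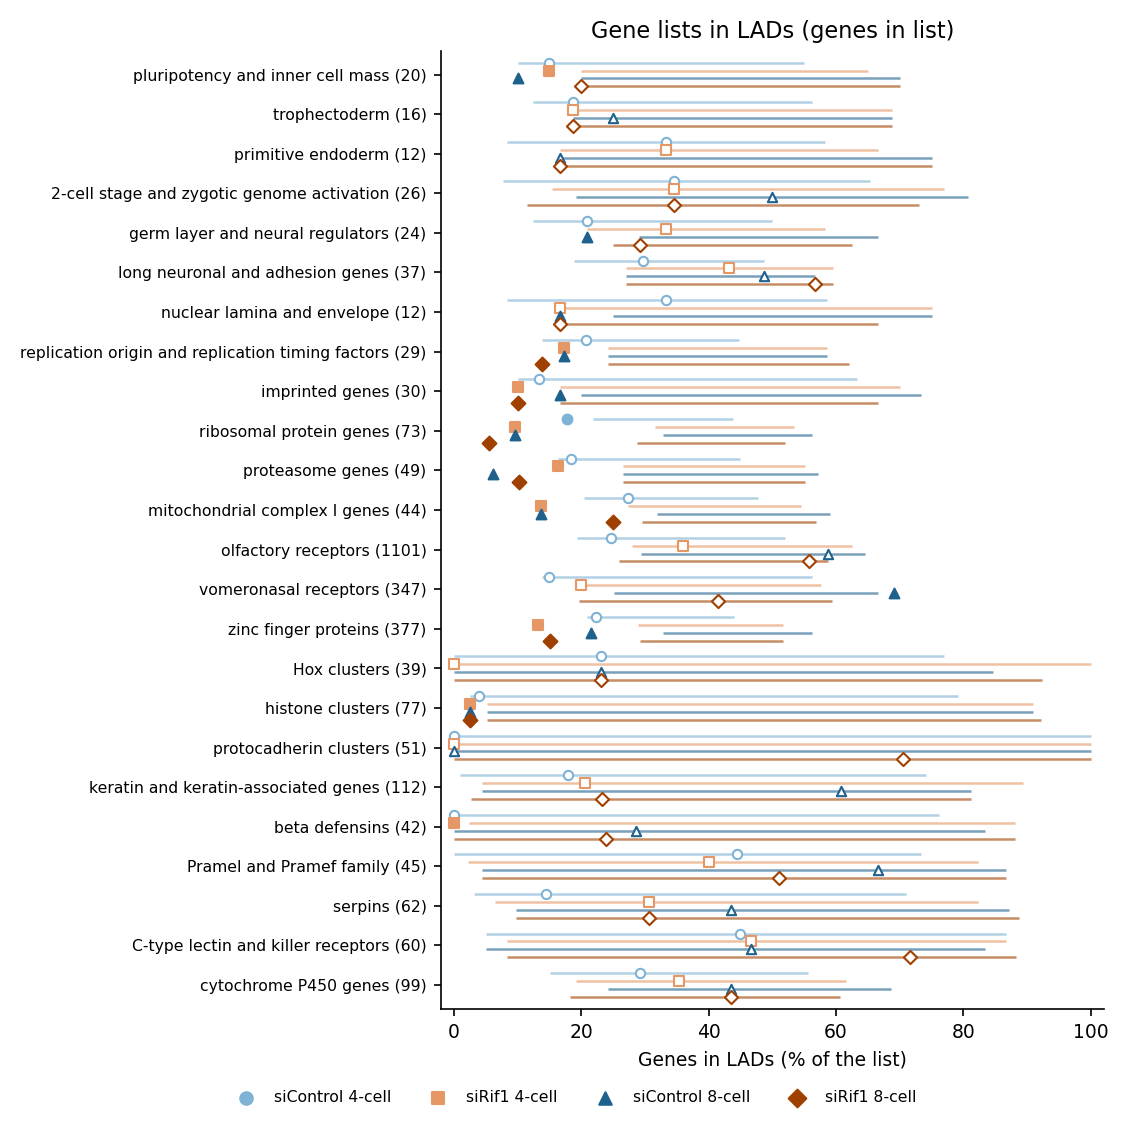
Percent of the genes of each list that lie in LADs (horizontal axis) in the 4 groups, for lists of at least 12 genes; lines are the central 95% range of positions from 10000 circular shifts, and filled symbols lie outside it. The vomeronasal receptors in siControl 8-cell embryos (69.2%) are the only share above its line.

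Genes of the nuclear lamina and envelope were mostly outside LADs. Lmnb1, which encodes lamin B1 (chromosome 18, 56707813 to 56753424), and Sun2 were LAD in siControl 4-cell embryos alone, and Sun1 in siControl 8-cell embryos alone. Tmpo was LAD in all lists but siControl 8-cell, and Syne1 in all 4. Lbr, Lmna, Ankle2, Lmnb2, Lemd3, Syne2 and Lemd2 were LAD in none. This list lay within the range of other genes in all 4 groups.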

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

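The counts of chromosomes by sign were chosen as tests after the result was seen, and the test on short stretches before. The following results stood out because siRif1 and siControl embryos differed one way at the 4-cell stage and the other way at the 8-cell stage, for gene lists by more than 10 points at each stage, and none of these differences between stages was tested, since each group is a pooled list. LAD bases in siRif1 minus siControl embryos differed by 252.7 Mb at the 4-cell stage and by -43.2 Mb at the 8-cell stage, a difference of -295.9 Mb. The number of LADs differed by 43 and by -8, a difference of -51. The median LAD length differed by 0.2 and by -0.1 Mb, a difference of -0.3 Mb. The share of complex I genes in LADs differed by -13.6 and by 11.4 percentage points, a difference of 25 points. It rests on few genes: of 44, 12 in siControl and 6 in siRif1 4-cell LADs, and 6 and 11 at the 8-cell stage. The share of serpin genes differed by 16.1 and by -12.9 points, a difference of -29.0 points. Of 62 serpin genes, 9 were in siControl and 19 in siRif1 4-cell LADs, and 27 and 19 at the 8-cell stage. Shares of 4 other lists also differed in opposite directions, but not by more than 10 points at each stage: keratin genes by 2.68 and -37.5 points, vomeronasal receptor genes by 4.90 and -27.7, olfactory receptor genes by 11.3 and -3.00 and proteasome genes by -2.04 and 4.08.

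For LAD bases, shifts of LAD borders by less than 300 kb as the main cause are argued against by the 9.09% of differing bases at the 4-cell stage that lie in stretches under 300 kb. Larger shifts of LAD borders stay open. Extensions at a border of a LAD of the other list made up 50.0% of the bases LAD in siRif1 4-cell alone and 51.1% of those LAD in siControl 4-cell alone. A few chromosomes as the cause of the 4-cell part are argued against by its sign on 17 of 19 chromosomes. The 8-cell part has the sign of the total on 10 of 19 and shrinks to -22.8 Mb without chromosome 7, so it may rest on few chromosomes. Differences in read depth, in the spread between replicates or in the threshold of the LAD caller, which could move coverage of a whole list, are open and were not tested, because the lists carry none of these. An effect of Rif1 depletion that depends on stage is also open.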

How the results depend on the processing

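The added alternatives (span of annotated genes, gene coordinates, odds ratio, correlation and share measures, shifts within siControl 4-cell bins, shifts along the order of genes) were chosen after the results were seen. No paired analysis was possible because each list pools its 3 replicates, which also means that no replicate could be left out. Autosomes alone changed nothing, as the lists hold no X, and percent of full chromosome length and base composition were not run. Bridged gaps kept the direction of the differences in LAD bases between lists. With LADs of at least 300 kb, siRif1 8-cell coverage was 42.1% and the share of genes in siControl 4-cell LADs 24.1%. With differing stretches of at least 300 kb the Jaccard indices were 55.2% (siRif1 and siControl, 4-cell), 59.0% (8-cell), 47.9% (control stages) and 55.4% (siRif1 stages), because short differences are dropped. Leaving out chromosomes in turn moved coverage to 32.3 and 33.6% (siControl 4-cell), 42.3 and 44.5% (siRif1 4-cell), 44.0 and 45.4% (siControl 8-cell) and 41.8% (siRif1 8-cell), and Jaccard indices to 54.8% (8-cell, without chromosome 1) and 51.9% (siRif1 stages, without chromosome 9). Differences in LAD bases became 219.8 Mb (4-cell, without chromosome 3), -22.8 Mb (8-cell, without 7), 245.9 Mb (control stages, without 4) and -31.4 Mb (siRif1 stages, without 1), and the last turned to 3.7 Mb without chromosome 10. The greater overlap of siRif1 4-cell with siControl 8-cell than with siControl 4-cell LADs had a log2 ratio of odds ratios of 0.077, and turned to -6.01 points as the share of each siControl list inside siRif1 4-cell LADs. All annotated genes gave 27.5, 29.8, 32.1 and 29.2% in LADs. Gene lists outside the range in siControl 4-cell LADs numbered 2 with random placement and 0 along the order of genes, which also gave 4 in siRif1 4-cell and 4 in siRif1 8-cell LADs, 2 for bases LAD in siRif1 4-cell and not siControl 4-cell, 0 in siControl 8-cell and not siRif1 8-cell, 2 in siRif1 8-cell and not siRif1 4-cell, and 1 in siRif1 4-cell and not siRif1 8-cell. The cause of the other shifts was not tested. Read depth is unknown, so what it limits cannot be given.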

Other observations

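The tests on odds ratios and correlations, on gene density of the siControl 4-cell list and on coverage for receptor genes, and the values on genes shared by all lists and on chromosome ends, were chosen after the results were seen, and the test without the leading receptor clusters before. LADs present in all 4 lists covered 409.2 Mb (17.2% of the span), and 828.1 Mb (34.7%) were outside LADs in all 4. The former held 4.76 and the latter 14.0 protein-coding genes per Mb. C-type lectin and killer receptor genes, expressed on immune cells, were LAD in all 4 lists in 24 of 60 cases (40%), Pramel genes in 15 of 45 and long neuronal genes in 10 of 37, against 9.66% of all protein-coding genes. Outside LADs in all 4 were 72 of 77 histone genes (93.5%) and 57 of 73 ribosomal protein genes (78.1%), against 57.4% of all protein-coding genes. These contrasts were not tested against ranges that keep the clustering of the families.

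The first 10 Mb of the span of each chromosome, which lie towards the centromere in the mouse, were 56.4% LAD in siRif1 4-cell embryos (SD 15.9 over 19 chromosomes), above the range of shifted lists (34.7 to 51.9%). The same part was 40.9% LAD in siControl 4-cell, 50.5% in siControl 8-cell and 43.2% in siRif1 8-cell embryos, each within its range, as were the last 10 Mb in all 4 lists (36.5, 41.4, 47.1 and 47.7% in siControl 4-cell, siRif1 4-cell, siControl 8-cell and siRif1 8-cell). The siControl 4-cell value for the first 10 Mb was just under the upper limit of its range (41.2%). Because the span starts and ends at a LAD of some list, which the shifts do not keep, LAD shares at its ends can be raised by this definition.

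A hypothesis from these data is that siRif1 4-cell embryos carry LADs of the next stage early, since their list overlapped siControl 8-cell more than siControl 4-cell LADs by 7.47 points of Jaccard index (4.03 to 10.6 over resampled chromosomes, 15 of 19 chromosomes), although the share of each siControl list inside siRif1 4-cell LADs goes the other way (-6.01 points, 74.2% of siControl 8-cell and 80.2% of siControl 4-cell LADs). Similar coverage of the lists cannot be told apart from it. The log2 ratio of odds ratios, which depends less on coverage, was 0.077 (-0.21 to 0.38). The difference in correlation of bins was 0.0379 (0.0038 to 0.0728). Unequal coverage lowers the highest correlation that siRif1 4-cell and siControl 4-cell LADs can reach, which can raise this difference. In another contrast, between lists of similar coverage, siControl 8-cell LADs overlapped siRif1 4-cell more than siRif1 8-cell LADs (log2 ratio of odds ratios 0.46, 0.26 to 0.68), which does not bear on siControl 4-cell LADs. The siControl 4-cell LADs overlapped siRif1 4-cell more than siControl 8-cell LADs, lists that also have similar coverage. This difference was 6.93 points of Jaccard index (4.74 to 9.31) and 0.84 in log2 ratio of odds ratios (0.58 to 1.12). The siRif1 4-cell list was thus nearer to the control 4-cell list than the control 8-cell list was. A siControl 4-cell list with weaker separation of LADs from the rest may also account for the greater overlap of siRif1 4-cell with siControl 8-cell LADs. That list was less depleted of genes than each of the other 3, by at least 0.60 (0.49 to 0.72) in log2 gene density ratio. A stage-specific LAD organisation in control 4-cell embryos would give the same value, so the hypothesis stays open.

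Olfactory and vomeronasal receptor genes (1448 genes in 62 clusters, neighbours within 1 Mb) were LAD in 22.4% of cases in siControl 4-cell, 32.1% in siRif1 4-cell, 61.3% in siControl 8-cell and 52.3% in siRif1 8-cell embryos. For the siRif1 lists, coverage alone is argued against, because siRif1 8-cell exceeded siRif1 4-cell embryos by 20.2 points (5.28 to 33.7 over resampled clusters) at similar coverage. That difference is part of the pattern itself. How much of the difference between control stages, whose coverage was unlike, comes from coverage was not tested. For the control stages, a few large clusters are argued against, because the difference between them, 38.9 points (26.9 to 50.5), was 35.5 points (21.5 to 51.0) without the 3 leading clusters on chromosomes 2, 7 and 10. Leading clusters were not removed from the siRif1 contrast. In it, the chromosome 2 cluster at 85330967 to 90401674 (222 genes) went from 13 to 137 LAD genes. In control embryos, 25 of 39 clusters of at least 5 genes held more LAD genes at the 8-cell stage, 5 fewer and 9 as many. Clusters were not counted in this way for the siRif1 lists. Reads shared between similar receptor genes and differences between replicates were not tested, and a change of receptor clusters with stage may remain one explanation among these.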
